A study of Homo sapiens with 6 samples.

How the data were processed

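RNA was measured in 6 libraries of U87MG cells, 3 from medium without serine and glycine and 3 from complete medium, after 24 h. Per the labels' protocols, cells were maintained in medium with 10% fetal bovine serum, and libraries were made from 500 ng of total RNA with the QuantSeq 3′ mRNA kit, which reads transcript ends, so that counts do not scale with transcript length. The authors deposited 1 table of raw read counts per gene symbol, with no normalization. The read aligner Bowtie2 was used, per the submitters' processing notes, which give no version. The counting program, genome build, annotation, strand setting and treatment of reads with several alignments are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by name, with 0 columns left unmatched.

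The table held 25737 rows with 24462 different gene symbols, and 0 rows named no gene. Each row was tested as deposited, although 286 symbols stood on more than 1 row, and those rows held 0.921% of the counts. Of the symbols, 21757 were current and 23376 were current or older symbols in the RefSeq gene table of human assembly GRCh38.p14, which was used for names only. No coordinates are given, since the build is not stated. Counts totalled 6249706 to 7247995 per library, and MALAT1, the most abundant gene, took 1.90% to 3.24%. Counts from genes with near-identical copies, such as MTRNR2L8 and the SNAR genes, and from overlapping antisense genes are uncertain.

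The comparison used edgeR 4.0.16 in R 4.3.3, with the filterByExpr function at its minimum count of 10, TMM scaling and the quasi-likelihood test of the group term, and Benjamini-Hochberg adjusted p under 0.05 as threshold. CPM values of genes were scaled by TMM, and log2 CPM used a prior count of 3. CPM of markers of other cell types used library totals alone. The biological coefficient of variation was 14.1%. Of 28 gene lists fixed before the data were examined, the 26 with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry.

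The text names genes by a rule set before the data were examined. It takes the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean CPM of at least 10 and no overlap between the groups, which gave none here. It always takes PHGDH, PSAT1, PSPH, SHMT1, SHMT2 and ATF4. From each list it takes up to 2 members past the threshold, or the member with the smallest p where none passed. Genes outside the rule, such as ASNS, CHAC1, TRIB3 and those described among the other observations, were chosen after their values were seen.

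The procedure was tested on simulated counts for the 13068 genes, with 200 genes changed. It recovered 43.3% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls among 166. With the labels of 1 library per group exchanged in the simulation, the procedure recovered 0 genes at each fold size. Simulated genes varied independently, without the sets of libraries that crossed the labels in the real data, as described below. The recovered shares therefore do not give the power for genes that followed those sets, such as PHGDH. The camera step gave the changed list a limma p of 8.45e-56 and gave 2 of 200 random lists a p under 0.05. Independent simulated genes meet the preset correlation by design, so this step cannot show false calls in lists whose members vary together. In the real data the estimated correlation was 0.86 for ATF4 targets, 0.83 for antioxidant genes, 0.84 for mitosis and 0.59 for ribosomal proteins.

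The alternatives were other library scalings, no low count filter, a stricter filter of CPM 5 in 3 libraries, the replicate number as a block, each library left out, rows with a shared symbol summed, DESeq2 1.42.0, limma-voom, a 2-fold minimum and a test against a 1.5-fold change. The leading principal component as a covariate, and the removal of deprived 2 and complete 1 together, were added after the data were seen. Whether a gene list kept its direction was read from the sign of its mean log2 fold change, a choice also made after the values were seen. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9. Outlier tests were not made, since groups had 3 libraries.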

Results

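Transcript abundance was measured in U87MG, an established human glioblastoma cell line, after 24 h in medium without serine and glycine or in complete medium that held both amino acids. Each condition had 3 libraries, named here by their labels as deprived 1 to 3 and complete 1 to 3. The libraries were made with a kit that reads the 3′ ends of polyadenylated transcripts. The total count was 7001929, 7066236 and 7102846 in deprived 1, 2 and 3, and 6249706, 7247995 and 6708761 in complete 1, 2 and 3. At this depth a count of 3 corresponded to 0.414 to 0.480 CPM, the count per 1000000 counts of the library, a floor that covers counting error only. The labels do not say whether the 3 libraries of a condition came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries matched within sampling noise, the chi-square statistic per gene being 2.42 to 15.5 over the pairs.

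The comparison of deprived with complete medium asked which transcripts respond when a glioblastoma line is kept in medium without serine and glycine. No gene passed the threshold by label, which does not show that none changed. The genes of serine synthesis and of the amino acid response differed more between libraries of the same label than between the labels. PHGDH, which catalyses the first step of serine synthesis from a glycolytic intermediate, stood at 201, 212 and 193 CPM in the libraries labelled deprived 1, deprived 3 and complete 1. It stood at 64.4, 59.4 and 59.0 CPM in the libraries labelled deprived 2, complete 2 and complete 3. PSAT1, the aminotransferase of the next step, followed the same order, with 279, 352 and 320 CPM in the former libraries and 61.4, 64.4 and 64.3 CPM in the latter. ATF4, the transcription factor that is translated when amino acids run short, measured 409, 477 and 414 CPM against 162, 174 and 154 CPM in the same order of libraries.

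Averaged by label, PHGDH was 159 ± 82.3 CPM (SD, n = 3) in deprived medium and 104 ± 77.4 CPM (SD, n = 3) in complete medium. Its log2 fold change of 0.62 had a standard error of 0.52 and an adjusted p of 0.999 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PSAT1 had a log2 fold change of 0.63 with a standard error of 0.70, and ATF4 one of 0.50 with a standard error of 0.44, both within the spread between libraries. With 1 library left out, the log2 fold change ran from 0.34 to 1.43 for PHGDH, from 0.19 to 1.84 for PSAT1 and from 0.21 to 1.09 for ATF4, highest without complete 1 for each. PSPH, the phosphatase that releases serine, ranged from 27.4 to 33.7 CPM in deprived 1, deprived 3 and complete 1 and from 19.8 to 20.9 CPM in the other libraries. SHMT2, the mitochondrial enzyme that converts serine to glycine, was at 120, 122 and 124 CPM in deprived 1, deprived 3 and complete 1 and at 69.9, 72.8 and 71.1 CPM in deprived 2, complete 2 and complete 3. Its cytosolic counterpart SHMT1 lay between 36.0 and 46.2 CPM in all 6 libraries, with a log2 fold change by label of 0.05 and a standard error of 0.12.

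**Figure D1:**
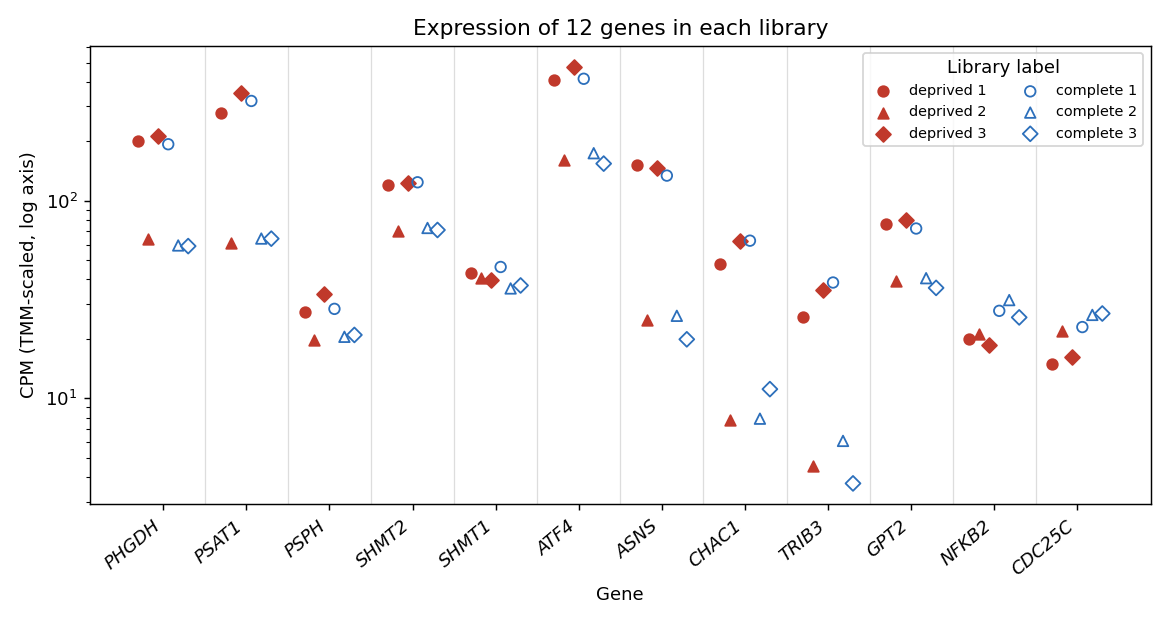
CPM of 12 genes in each library on a log axis, with filled red symbols for libraries labelled deprived, open blue symbols for libraries labelled complete, and 1 symbol per library. PHGDH, PSAT1, ATF4 and SHMT2 were high in deprived 1, deprived 3 and complete 1, while SHMT1 lay between 36.0 and 46.2 CPM throughout.

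Of 13068 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 247, or 1.89%, had an unadjusted p under 0.05. That is below the share of 0.05 that a test gives when nothing differs. The p-values by label were therefore conservative, and such counts do not give a number of changed genes. DESeq2 also called 0 genes, with 140 of 19472 under an unadjusted p of 0.05, and limma-voom called 0 with 251. The 3 deprived and the 3 complete libraries did not overlap in 911 genes, or 6.97%, where chance gives 10%. Deprived 1, deprived 3 and complete 1, a set singled out after its values were seen, did not overlap the rest in 35.97%. Each other division into sets of 3 gave 6.08% to 8.85%, a range that holds the share by label. A gene without ties separates in only 1 of the 10 divisions, so the large share of the crossing set lowers all the others. The share by label under 10% therefore tests nothing about the medium.

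Named genes with smaller spread also missed the threshold. NFKB2, a subunit of the transcription factor NF-kB, measured 19.9 ± 1.31 CPM (SD, n = 3) in deprived and 28.3 ± 2.91 CPM (SD, n = 3) in complete medium. Its log2 fold change was -0.50 with a standard error of 0.13, and its edgeR adjusted p was 0.999. CDC25C, a phosphatase that drives entry into mitosis, had a log2 fold change of -0.53 with a standard error of 0.17, and HSD17B7, an enzyme of cholesterol synthesis, one of -0.49 with a standard error of 0.20. GLA, the lysosomal alpha-galactosidase, had a log2 fold change of 0.59 with a standard error of 0.20, its libraries overlapping between the labels. The other named genes had log2 fold changes from -0.75, for the immediate early gene FOSB, to 0.70, for the tight junction gene CLDN4, both of which lay below 4 CPM in every library. All 32 named genes had an edgeR adjusted p of 0.999.

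Among 26 gene lists fixed before the data were examined, limma's camera test with a preset correlation of 0.01 called 4 by label. ATF4 targets of the amino acid response were higher in deprived medium, with a mean log2 fold change of 0.43, 29 of 30 members positive and a limma camera adjusted p of 0.00522. The adjusted p = 0.859 with an estimated correlation, and the mean ran from 0.14 to 1.46 with 1 library left out. NRF2 targets and antioxidant enzymes were higher, with a mean of 0.26, 19 of 20 members positive and a limma camera adjusted p of 0.0199. Its adjusted p = 0.859 with an estimated correlation, and the mean ran from 0.13 to 0.58 with 1 library left out. Genes of mitosis were lower, with a mean of -0.12, 27 of 29 members negative and a limma camera adjusted p of 0.00556. That list too had an adjusted p = 0.859 with an estimated correlation, and a mean from -0.26 to -0.05 with 1 library left out. Ribosomal protein genes were lower, with a mean of -0.05, 60 of 79 members negative and a limma camera adjusted p of 0.0199, and again an adjusted p = 0.859 with an estimated correlation. Its mean ran from -0.10 without complete 1 to 0.0002 without complete 2, which turned its direction. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. In each of the 26 lists, 0 members passed adjusted over all genes and 0 passed adjusted over the list alone. All 4 calls were lost when deprived 1, deprived 3, complete 2 or complete 3 was left out, whereas leaving out deprived 2 or complete 1 gave 10 called lists each.

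A list score is the mean deviation of the members from their 6-library mean on the log2 CPM scale, and several lists set the same libraries apart as PHGDH did, while others, such as cholesterol synthesis with scores from -0.03 to 0.03, did not. The ATF4 list scored 0.69, 0.88 and 0.87 in deprived 1, deprived 3 and complete 1, and -0.79, -0.81 and -0.85 in deprived 2, complete 2 and complete 3. The 3 highest values lay in deprived 1, deprived 3 and complete 1 for 29 of its 30 members. Over all 13068 genes the same was true of 2393, or 18.3%, and the 3 lowest values lay there for 2307, or 17.7%, these libraries having been singled out after their values were seen. The antioxidant list scored 0.41, 0.38 and 0.36 against -0.39, -0.38 and -0.38 in the same order, with 19 of 20 members highest in those libraries. The list of amino acid transporters scored 0.32, 0.43 and 0.38 against -0.39, -0.39 and -0.35, with 11 of 22 members highest and 2 lowest in those libraries. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, scored 0.13, 0.24 and 0.20 against -0.19, -0.20 and -0.18, with 12 of 20 members highest and 2 lowest there. Autophagy and lysosome genes scored 0.18, 0.18 and 0.20 against -0.19, -0.18 and -0.19, with 20 of 30 members highest. Genes of mitosis scored -0.16, -0.21 and -0.16 against 0.18, 0.15 and 0.20, and genes of DNA replication -0.10, -0.19 and -0.20 against 0.17, 0.17 and 0.16, with 25 of 29 and 22 of 31 members lowest in those libraries.

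**Figure D2:**
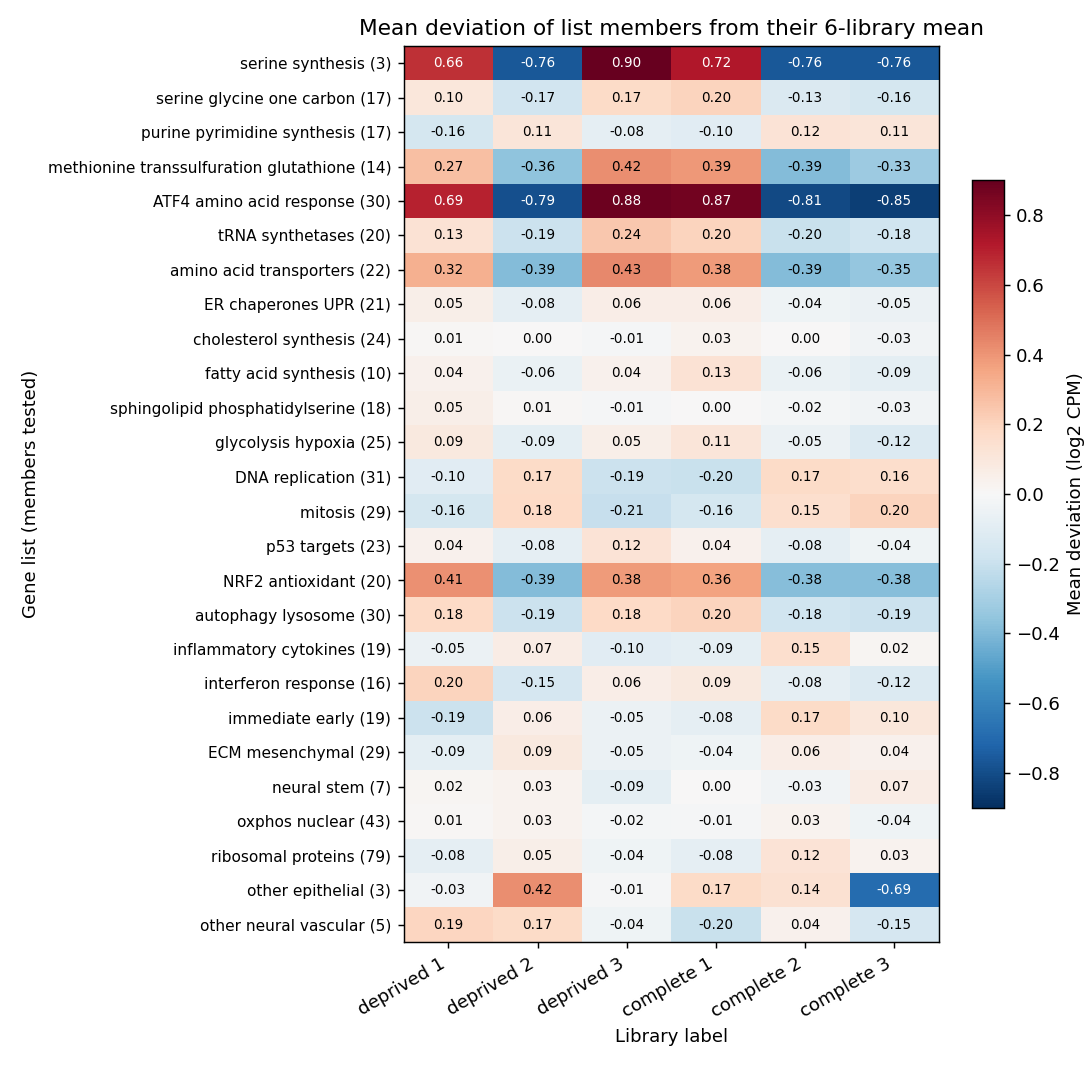
Mean deviation of the tested members of each of 26 gene lists from their 6-library mean, in log2 CPM, for each library by its label, with red above and blue below 0. The ATF4 list ranged from -0.85 in complete 3 to 0.88 in deprived 3, and complete 1 at 0.87 lay beside the latter.

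By label, the other lists were not called, with limma camera adjusted p from 0.0674 for DNA replication to 0.981 for fatty acid synthesis. The 3 genes of serine synthesis had a mean log2 fold change of 0.49 and a limma camera adjusted p of 0.285. With the correlation estimated, at 0.967, the limma camera adjusted p was 0.859, and the calls of this list that follow kept the preset correlation. The mean ran from 0.19 to 1.22 with 1 library left out. The list was called without deprived 2, with a mean of 0.82 and a limma camera adjusted p of 0.0261. It was also called without complete 1, with a mean of 1.22 and a limma camera adjusted p of 0.0396. Over its alternatives the limma adjusted p ranged from 0.000261, without both libraries, to 0.969, with the leading principal component as a covariate. Both of those fits were added after the data were seen, and the lowest limma adjusted p among planned settings was 0.0261. Positive log2 fold changes were found for 15 of 22 amino acid transporters, 14 of 20 tRNA synthetases, 25 of 30 autophagy and lysosome genes, 11 of 18 sphingolipid and phosphatidylserine genes and 12 of 21 endoplasmic reticulum chaperones. They were found for 4 of 17 purine and pyrimidine synthesis genes, 7 of 31 DNA replication genes, 6 of 19 inflammatory cytokine genes, 6 of 19 immediate early genes, 12 of 29 extracellular matrix genes and 2 of 7 neural stem genes. Interferon-stimulated genes were positive in 10 of 16 and respiratory chain subunits in 22 of 43. For enzymes of serine, glycine and one-carbon metabolism, positive in 8 of 17, the mean was 0.07, the median -0.01 and the camera direction down. Methionine and glutathione genes, positive in 8 of 14, had a mean of 0.16, which ran from 0.02 to 0.61 with 1 library left out, and a camera direction of down. Cholesterol synthesis genes, positive in 11 of 24, and fatty acid synthesis genes, positive in 3 of 10, likewise had a mean above 0, a median below 0 and a camera direction of down. Glycolytic and hypoxia genes, positive in 12 of 25, and p53 targets, positive in 11 of 23, had a mean above 0, a median below 0 and a camera direction of up.

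Markers of other cell types were near or below the floor for most genes, and the lists of them gave no call by label with the low count filter. Without that filter, the list of neuronal, oligodendrocyte and endothelial markers was called, with a mean log2 fold change of 1.10 and a limma camera adjusted p of 0.0327, against a range of 0.0327 to 0.940 over its alternatives; most of its members were near or below the floor. The neuronal genes SNAP25, SYT1 and GAD1 were above it, SYT1 at 31.2 to 37.0 CPM and GAD1 at 11.4 to 18.0 CPM. SNAP25, a protein of synaptic vesicle release, was at 30.8, 31.4 and 25.6 CPM in deprived 1, deprived 3 and complete 1 and at 42.2, 40.6 and 39.1 CPM in deprived 2, complete 2 and complete 3. The leukocyte marker PTPRC reached at most 0.563 CPM, and the T cell genes CD3D and CD3E, the epithelial cadherin CDH1 and the keratin KRT5 had 0 counts in all 6 libraries, which allows up to 0.480 CPM. CD68, a lysosomal protein of macrophages that many cell lines express, lay between 49.9 and 71.2 CPM. The epithelial markers tested were positive in 2 of 3 and the neural and vascular markers in 4 of 5. The 13 mitochondrially encoded genes could not be tested, since 0 of them were in the count table, and the leukocyte list was left out with 2 members tested.

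The first principal component held 51.4% of the variance and placed deprived 1, deprived 3 and complete 1 at 20.5, 21.1 and 22.1, and deprived 2, complete 2 and complete 3 at -21.4, -20.5 and -21.8. MALAT1, a nuclear noncoding RNA and the most abundant gene, took 3.24%, 3.11% and 2.75% of the counts in deprived 1, deprived 3 and complete 1 and 1.93%, 1.92% and 1.90% in deprived 2, complete 2 and complete 3, and the 10 most abundant genes took 7.69%, 7.91% and 7.43% against 6.83%, 6.86% and 6.96%. Without deprived 2 and complete 1, libraries left out after their values were seen, 2096 genes passed the edgeR test, 1126 higher and 970 lower in deprived medium; because these libraries were chosen by their values, that count is no independent test of the medium.

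**Figure D3:**
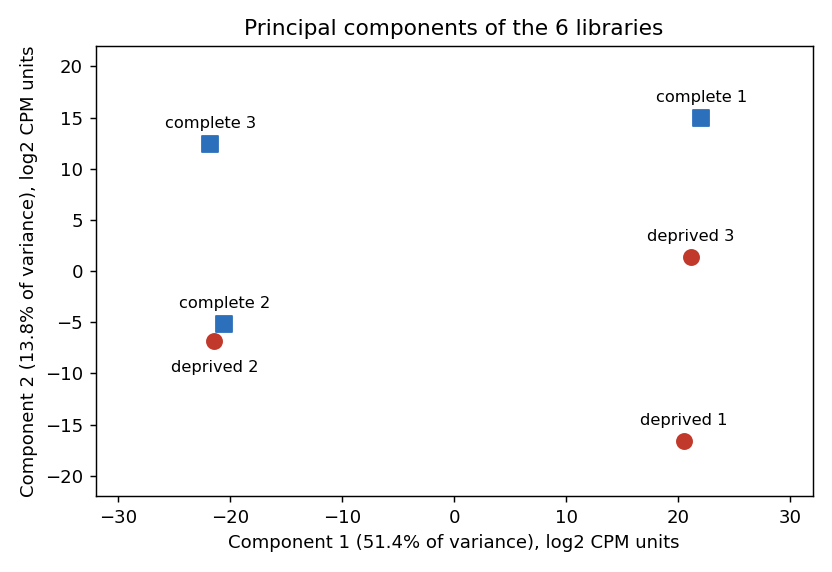
Scores of the 6 libraries on the first and second principal components of log2 CPM, with red circles for libraries labelled deprived and blue squares for libraries labelled complete. On the first component complete 1 lay at 22.1, beside deprived 1 and deprived 3, and deprived 2 lay at -21.4, beside complete 2 and complete 3.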

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

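The fits with the leading principal component as a covariate and without deprived 2 and complete 1 together were chosen after the result was seen; the other settings were planned. The count of genes called by label stayed at 0 under every planned setting, including each library left out, but was 3 with the leading component as a covariate and 2096 without both libraries, which were picked by their values. At an unadjusted p under 0.05, edgeR gave 1037 of 13296 genes without deprived 2 and 1141 of 13282 without complete 1, against 247 of 13068 with all libraries. The count of called gene lists was 4 with all libraries, 0 to 10 with 1 library left out, 0 with an estimated correlation, 0 with fry, 0 with the leading component and 12 without both libraries. No filter gave 5 lists, the added one being the neural and vascular markers at a mean of 1.10, and the stricter filter 6, DNA replication and autophagy being added. The labels do not say whether equal replicate numbers mark pairs. Deviations of same-numbered libraries from their label means correlated at 0.384, 0.381 and -0.281 across genes. The signs followed the side of the first principal component, with -0.597 between deprived 2 and complete 1, so these values cannot settle a pairing. With the replicate number as a block, 0 genes and 6 lists were called, DNA replication and autophagy being added. In that edgeR fit 429 genes had an unadjusted p under 0.05. Not every library correlated best with its own number. Depth limits genes near 0.414 to 0.480 CPM.

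The mean log2 fold changes that changed sign follow. With the leading component, which takes up the difference between the crossing libraries, they were -0.01 for the ATF4 list, against 0.43 without it, -0.0366 for one-carbon enzymes, -0.0192 for methionine and glutathione genes, -0.0017 for tRNA synthetases, -0.0238 for chaperones, -0.0040 for cholesterol, -0.0392 for fatty acid synthesis, -0.0234 for glycolysis, 0.0211 for DNA replication, -0.0050 for autophagy, -0.0002 for interferon genes and 0.0077 for extracellular matrix, and -0.0014 for SHMT1 and -0.0223 for SHMT2, against 0.22 without it. For the other settings the cause was not tested. Library totals alone gave -0.0027 for fatty acid and -0.0059 for cholesterol synthesis. Upper quartile scaling gave -0.0017 for cholesterol synthesis. No filter gave 0.0473 for cytokines, 0.0608 for neural stem genes and -0.0732 for cholesterol synthesis. Without both libraries, the respiratory chain had -0.0078.

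With each library left out in turn, the mean ranged from -0.0051 to 0.2339 for one-carbon enzymes, -0.0095 to 0.0566 for chaperones, -0.0125 to 0.0244 for cholesterol, -0.0324 to 0.0829 for fatty acid synthesis, -0.0165 to 0.1067 for glycolysis, -0.0037 to 0.1013 for p53 targets, -0.0201 to 0.163 for interferon genes, -0.1069 to 0.0054 for extracellular matrix, -0.0046 to 0.0302 for the respiratory chain, -0.1016 to 0.0002 for ribosomal proteins, -0.0262 to 0.4184 for epithelial markers and -0.0212 to 0.1678 for SHMT1.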

Other observations

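The ranking of variable genes, the count of splits, the count of list members that set complete 1 and deprived 2 apart, and the bound on the ATF4 list with the leading component as a covariate were chosen after the result was seen. Among the 40 genes with the largest spread over the 6 libraries at a mean CPM of 10 or more, 38 had their 3 highest values in deprived 1, deprived 3 and complete 1, and 21 of the 40 were on a list fixed before the data were examined. Of the fixed list of methionine, transsulfuration and glutathione genes, 7 of 14 members were highest in those libraries, and its spread lay at percentile 45.4 of random lists. CTH, which makes cysteine from cystathionine, stood at 34.3, 43.5 and 34.8 CPM in deprived 1, deprived 3 and complete 1 and at 5.26, 2.91 and 5.94 CPM in deprived 2, complete 2 and complete 3. SLC7A11, the cystine importer, was at 278, 324 and 327 CPM against 38.1, 41.0 and 40.4 CPM, although its antisense partner SLC7A11-AS1 ran alongside and their reads cannot be separated without a stated strand setting. CHAC1, which degrades glutathione, was at 47.9, 62.5 and 62.8 CPM against 7.82, 7.89 and 11.1 CPM.

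Genes outside the fixed lists followed the same order. UNC5B, a netrin receptor, measured 153, 200.2 and 172 CPM in deprived 1, deprived 3 and complete 1 and 27.7, 27.3 and 30.9 CPM in deprived 2, complete 2 and complete 3. GPNMB, a lysosomal glycoprotein, measured 53.1, 58.7 and 47.2 CPM against 14.4, 13.8 and 15.7 CPM, and FBXO32, a ubiquitin ligase subunit of muscle wasting, 123, 121 and 120 CPM against 39.2, 36.0 and 34.5 CPM. The opposite order was found for 2 of the 40 genes. G0S2, an inhibitor of lipolysis, measured 32.5, 33.5 and 34.3 CPM against 123, 119 and 115 CPM, and the cytokine IL11 13.0, 11.1 and 10.8 CPM against 39.1, 38.2 and 33.4 CPM.

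No gene was called by label, while the libraries formed sets that crossed the labels: all 10 splits into sets of 3 gave at least the 0 genes of the labelled split, as a count of 0 makes certain, so this count tests nothing, and 10 splits are too few for a share under 0.05, but the highest other split, deprived 1, deprived 3 and complete 1 against the rest, gave 3124, which points to a structure of the samples. Library size is argued against, since thinning all libraries to the smallest total left 3051 genes in that split. For the ATF4 list, a response by label added on top of a batch with correct labels is also argued against. Its mean log2 fold change by label was -0.01 with the leading component as a covariate. Its score then had a label effect of 0.0086 with a standard error of 0.06. That component was drawn from the same values, which the ATF4 targets helped to set. Each set of 3 held only 1 library of its rarer label, and an amino acid response that did not add to the batch stays open. Exchanged labels of complete 1 and deprived 2 remain an open hypothesis that no value here separates from a batch that moved the same genes. The serine synthesis, ATF4 and tRNA synthetase lists had 53 tested members. Of these, 44, or 83.0%, had deprived 1, deprived 3 and complete 1 all above the rest, 29 of them ATF4 list members. That count restates the pattern, and such a batch would give the same count. A batch with correct labels and some other response to the medium also remains open, since 3 genes were called with the leading component as a covariate. They were SNAR-A13 at -0.63, SNAR-A8 at -0.51 and RNU4ATAC at -0.35 on the log2 scale. These calls met a bound set beforehand, which names the crossing sets and so was written after those sets were seen. All 3 are short noncoding RNAs, and counts of the near-identical SNAR genes are uncertain. All 3 also overlapped between the labels, with deprived 3 above complete 2. The values were 51.9 against 44.6 CPM for SNAR-A13, 209 against 166 CPM for SNAR-A8 and 1255 against 1112 CPM for RNU4ATAC. For a batch with no response to the medium, the spread of the ATF4 list was predicted to lie below percentile 95 of 10000 random lists. That prediction too was set beforehand but after the crossing sets were seen. The spread lay at percentile 100, so the prediction failed. A batch of depleted culture medium could still move the same genes. Such a batch cannot be told apart from exchanged labels, because no record of how the libraries were handled was used here.

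Gene lists were called by label while no gene was, and a candidate explanation is that the sets of 3 are unevenly shared between the labels. Deprived medium had 2 and complete medium 1 of the libraries with high ATF4 targets. With the leading component as a covariate 0 of 26 lists were called, against 4 without it. That component was drawn from the same values, and most members of the called lists followed it. The loss of the calls was thus close to built in and does not test the explanation. Because the labels shared the sets unevenly, the calls of the ATF4, antioxidant, mitosis and ribosomal protein lists give no independent evidence on the medium while the labels of these libraries are in doubt.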
